A study of Mus musculus with 4 samples.

How the data were processed

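Single-cell RNA sequencing was carried out on GFP-positive mouse leukaemia cells sorted from bone marrow. Per the labels, the leukaemias came from c-Kit-positive marrow cells with a floxed Hif-1alpha gene and a tamoxifen-inducible Cre, transduced with a retrovirus carrying MLL-AF9, a fusion oncogene of acute myeloid leukaemia. The series holds 4 samples, 1 in each combination of Hif-1a genotype (wild type or knockout) and treatment (PBS or chemotherapy). Per the labels' protocols, libraries were made with the 10x Chromium 3' V2 kit, which counts the ends of transcripts by unique molecular identifiers (UMIs). Reads were processed with Cell Ranger 1.3 against the mm10 build, per the submitters' processing notes. The notes name Seurat 2.3.4 for later steps and the series design text names Seurat 1.4. The gene annotation is not given in the sources used here.

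The deposited table holds UMI counts per gene and cell barcode, whole numbers with no normalization, for 27998 gene symbols and 5664 barcodes. Each barcode ends in a suffix from 1 to 4, and nothing in the sources used here says which suffix is which sample. Suffixes were therefore treated as 4 samples with no assigned group. The 4 planned pairwise comparisons of genotype or treatment, the difference of the chemotherapy effect between genotypes, and the naming of genes by those ratios were not made. Each suffix has its own value throughout, and classes of cells were compared with the other cells of the same suffix. No p-value was computed, since cells are not replicates.

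Cells with at least 500 UMIs and at most 10% mitochondrial UMIs were kept, which left 5456. No barcode lay under the UMI minimum (the lowest had 1189 UMIs), so the mitochondrial limit removed all 208 excluded barcodes. The 4 suffixes held between 7644436 and 9932649 UMIs in kept cells. A gene with no UMI in a suffix has an upper limit of 3 counts, between 0.302 and 0.392 CPM (UMIs of a gene scaled to a common total). Intervals are exact Poisson for CPM, exact conditional binomial for ratios and exact binomial for shares, at 95%, and cover counting error only.

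Counts were log-normalised to 10000 UMIs per cell with scanpy 1.11.5 in Python 3.11.15. Clusters came from 2000 variable genes, 30 principal components, 15 neighbours and the Leiden method at resolution 1, with all suffixes together. The filter, the clustering settings, the gene lists, the cell type markers and the rule for named genes were fixed before the data were examined. The scoring that turns markers into a name, the comparison of a class with the other cells and its minimum of 30 cells were set afterwards. A cluster was called after a cell type where at least 3 of its markers were 2-fold or more above all other cells at 20 CPM or more, where that type had more such markers than any other, and where it also had the most markers among the 10 leading genes by fold (10 CPM added to both sides). Scrublet, run on each suffix, marked 28 of 5456 cells (0.513%) as doublets, a share close to the level at which a caller is taken not to have worked, and no doublets were removed in the main results.

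UMI counts were summed over the cells of a class and over the other cells of the same suffix, divided by their totals, and compared as log2 of (CPM + 1) over (CPM + 1), in suffixes with at least 30 cells on both sides. The value of a gene is the median over those suffixes. It was first computed as a mean, and the median replaced it after both had been seen. The value of a gene list is the median over members with a mean of at least 5 CPM, set beside 10000 random lists of the same size matched on mean expression in 20 bins. A member was counted as higher or lower where it differed at least 1.2-fold, went the same way in each usable suffix and had a pooled counting interval that excluded 1. These counts describe size in these cells and are no test. Examples named from a list are the 2 members with the highest mean CPM and the 2 others with the largest log2 ratio, of which a few are left out of the text. The 5 leading genes by fold are named for each cluster, as was planned for columns without a sample. Some of the genes compared also took part in the clustering, so their ratios are not independent of it.

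On simulated counts with the real gene means, depths and class sizes, 200 of 8244 genes were changed. For the neutrophil-like class, the counting rule found 100% of genes raised 3-fold and 92% of genes lowered 3-fold. At 1.5-fold it found 78% of the raised and 56% of the lowered genes, and it counted 3.32% of unchanged genes. For the granulocyte precursor-like class it counted 1.72% and for the monocyte-like class 3.21% of unchanged genes. The simulated counts were Poisson draws from the mean profile of each suffix, with the class labels fixed. They held no other variation between cells, no clustering and no shift shared by most genes. These shares are therefore no error rates for the counts in the real classes.

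For cycling, each cell was thinned to 2000 UMIs and counted where it had at least 2 UMIs over the S phase or the G2 and M phase list. Thinning left out 29, 20, 45 and 20 cells of suffixes 1 to 4. Alternatives covered the cell filter, scaling (TMM from edgeR 4.0.16 and median of ratios factors from DESeq2 1.42.0, in R 4.3.3), the weight of cells, thinning, the pseudocount, doublets, the clustering settings and the cycling rule. Gene positions are from GENCODE M21 on GRCm38, the assembly that mm10 names.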

Results

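Hif1a transcripts were counted in cells of each barcode suffix, at 38.5 CPM (95% interval 34.2 to 43.1) in suffix 1, 35.2 (31.3 to 39.5) in suffix 2, 29.5 (26.2 to 33.1) in suffix 3 and 26.5 (23.2 to 30.2) in suffix 4. Hif1a (ENSMUSG00000021109.13) encodes the oxygen-regulated subunit of the transcription factor HIF-1 and lies on chromosome 12 from 73901375 to 73947530, plus strand, in GRCm38. The knockout removes a floxed part of the gene, and the labels do not say which exons. A 3' count outside the deleted part can persist after deletion, so these levels check nothing about the genotype labels.

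The leukaemia cells had been collected from the bone marrow of C57BL6 mice aged 11 weeks. Recipients of primary MLL-AF9 leukaemias were given 1 mg tamoxifen or vehicle for 5 days, starting 10 days after transplantation. Chemotherapy was cytarabine at 100 mg/kg for 5 days with doxorubicin at 3 mg/kg for 3 days, and marrow was taken 3 days after treatment ended. The series title names treatment efficacy after Hif-1alpha deletion, which calls for comparing genotypes with and without chemotherapy. Because barcode suffixes are not tied to the 4 samples, no such comparison was made, and differences between suffixes are given without a condition. There were 1174, 1251, 1625 and 1406 kept cells in suffixes 1 to 4, with median depths of 6094, 6435, 5315 and 5324 UMIs per cell. No sample had a replicate.

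Cells with markers of several myeloid stages were found. Of 14 clusters, 4 met the rule for a name. Clusters 0 and 7 were granulocyte precursor-like. Cluster 0 was led by Nkg7, Cebpe, Rgcc, Fkbp11 and Vat1, and cluster 7 by Ms4a3, Nkg7, Lect1, Elane and Mrgpra2b. Elane, the primary granule protease neutrophil elastase, stood at 17197 CPM in cluster 7 and 3309 CPM in all other cells. Cluster 12 was neutrophil-like and was led by Ngp, Camp, S100a9, BC100530 and Gm5483. S100a9, a subunit of calprotectin, stood at 49783 CPM there and at 136 CPM elsewhere. Cluster 6 was monocyte-like and was led by Ifitm3, Apoe, S100a6, Cd74 and S100a4, with 13 raised monocyte markers that included Csf1r, Ccr2, Fn1 and Klf4. The macrophage markers Adgre1, Hmox1, Apoe and Cd68 were raised in cluster 6 as well.

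The other 10 clusters stayed unnamed. Cluster 3 was led by Cpa3, Npy, Ptprcap, Mcpt8 and Adgrg1, where Cpa3 and Mcpt8 are proteases of mast cells and basophils. Its raised markers were divided between 6 of stem and progenitor cells and 3 of basophils and mast cells. Cluster 10 was led by Gsn, Cpa3, Tsc22d1, Rab19 and Nfil3, and cluster 11 by Lpl, Wfdc17, Tgm3, Cyp4f18 and Hacd4. Cluster 11, with 17.0% and 16.8% of the cells of suffixes 3 and 4, had 5 raised monocyte and 3 raised macrophage markers, of which 0 and 2 were among its 10 leading genes. It is thus part of the other cells to which monocyte-like cells are compared. Cluster 9 was led by Prg2, Prg3, Clec4a2, Mogat2 and Retnla, of which Prg2 and Prg3 encode eosinophil granule proteins. Cluster 13, with 42 cells, was led by the interferon-induced genes Ifit3, Irf7, Isg15 and Rsad2, followed by Cd74. It had 13 raised monocyte markers, as many as cluster 6, and stayed unnamed because more dendritic cell and MHC class II markers (2) than monocyte markers (1) were among its 10 leading genes. Cluster 4 was led by Cenpa, Ccnb2, Cdc20, Hist1h2bc and Cdkn3, cluster 5 by Hist1h2ap, Ube2c, Nusap1, Cenpf and Top2a, and cluster 8 by Rrm2, 2810417H13Rik, Ung, Tk1 and Rad51ap1. Cluster 2 was led by Hist1h2bc, Mpo, Fabp5, Myc and Bsn, and cluster 1 by Fbxw4, Cd28, Gpx3, Gpr183 and Hist1h2bc, none of them over 1.72-fold in cluster 1.

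Markers of lineages outside the myeloid series were low. Summed over each list, erythroid genes had a median of 36.5 CPM over the suffixes (range 22.8 to 50.4) and B cell genes 79.0 CPM (67.3 to 89.1). T and NK cell genes stood at 5.29 CPM (3.42 to 15.7), megakaryocyte genes at 4.09 CPM (3.73 to 7.72) and stromal and endothelial genes at 85.5 CPM (80.2 to 98.0). Granulocyte precursor genes reached 14027 CPM (9565 to 21058) and monocyte genes 7829 CPM (4156 to 11462).

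Granulocyte precursor-like cells made up 23.6% (exact binomial 95% interval 21.2 to 26.1) of kept cells in suffix 1, 28.6% (26.1 to 31.2) in suffix 2, 4.12% (3.21 to 5.21) in suffix 3 and 3.49% (2.59 to 4.58) in suffix 4. Monocyte-like cells were 2 of 1174 (0.170%) in suffix 1, 10 of 1251 (0.799%) in suffix 2, 17.3% (15.5 to 19.2) in suffix 3 and 14.6% (12.8 to 16.5) in suffix 4. Neutrophil-like cells were 0.426% (0.138 to 0.991), 0.799% (0.384 to 1.47), 8.31% (7.01 to 9.76) and 7.25% (5.95 to 8.74) of suffixes 1 to 4. The share of granulocyte precursor-like cells depended on the clustering, since its median over suffixes of 13.9% became 3.09% when cell cycle, ribosomal and mitochondrial genes were kept out of the variable genes. Monocyte-like cells had a median of 7.69%, which became 20.98% at Leiden resolution 0.5, and no cluster met the name when no cells were filtered.

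**Figure D1:**
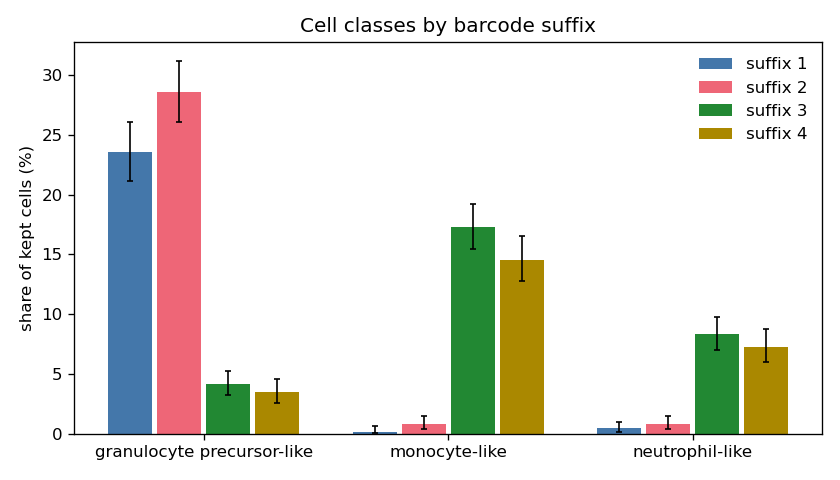
Share of kept cells (%) in each named class, by barcode suffix. Bars are shares and whiskers exact binomial 95% intervals for counting error. Granulocyte precursor-like cells range from 3.49% to 28.6%, monocyte-like cells from 0.170% to 17.3% and neutrophil-like cells from 0.426% to 8.31%.

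In granulocyte precursor-like cells, cell cycle genes were lower than in the other cells of the same suffix. For each class, the other cells include clusters 4, 5 and 8, led by cell cycle genes such as Ccnb2, Top2a and Rrm2. The clustering can thus place cycling cells outside a class, and how much of the gap this makes was not tested. Of 52 measured G2 and M phase genes, 44 were lower and 0 higher, with a median log2 ratio of -1.48. It was -1.04 with a pseudocount of 5 CPM and -0.73 when the described lists were kept out of the variable genes, 19 of which were G2 and M phase genes in the main clustering. Nusap1 and Hmmr, which act on the mitotic spindle, stood at -2.78 and -2.76, Hmgb2 at -0.77 and Cks2 at 0.05. Of 42 S phase genes, 24 were lower and 0 higher (median -0.50), with Slbp at -0.44, Tipin at -0.41, Brip1 at -1.36 and E2f8 at -1.32. This median was -0.28 when the described lists were kept out of the variable genes. Interferon response genes had 12 of 23 members lower (median -0.52), with B2m at -0.49, H2-D1 at -0.65, Ifitm3 at -2.79 and Irf7 at -1.59. By suffix the interferon median was -0.32, -0.31, -0.71 and -1.02. In suffixes 3 and 4 the other cells include the monocyte-like cluster 6 (281 and 205 cells) and the interferon-led cluster 13 (20 and 22 cells). Suffixes 1 and 2 held 2 and 10 cells of cluster 6 and 0 of cluster 13. How much of the interferon gap these 2 clusters make was not tested. In the list of MLL-AF9 associated leukaemia genes 12 of 24 were lower and 3 higher (median -0.54), with Flt3 at -1.87, Bcl2 at -1.60, Lmo2 at -0.26 and Cdk6 at 0.29. Stem and progenitor genes had 6 of 16 lower and 2 higher (median -0.44), with Spi1 at 0.06, Lyl1 at -0.09, Cd34 at -1.90 and Gfi1, a repressor needed for granulocyte formation, at 1.56. Among p53 targets 12 of 23 were lower and 1 higher (median -0.42), with Rps27l at -0.07, Xpc at 0.15, Cdkn1a at -1.96 and Psrc1 at -1.70. Among immediate early and handling stress genes 8 of 18 were lower and 0 higher (median -0.35), with Hspa8 at -0.39, Hsp90aa1 at -0.07, Klf2 at -2.42 and Klf6 at -1.25. By suffix the stress median was -0.19, -0.12, -0.74 and -0.56, the p53 target median -0.18, -0.44, -0.70 and -0.59, and the stem and progenitor median -0.16, -0.54, -0.51 and -0.28. These 7 lists lay below the central 95% of random lists. The stress list was inside that range when the described lists were kept out of the variable genes (median -0.02) and when cells were thinned to 2000 UMIs (-0.34). The stem and progenitor list was inside it thinned (-0.37) and with means over suffixes (-0.33), and its median was -0.76 with no filter on cells.

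Ribosomal protein genes and glycolysis genes lay above the central 95% of random lists in the same class. The median of 79 ribosomal protein genes was 0.18, with Rpl32 at 0.31, Rps27a at 0.36 and Rpl36a at 0.34, and 6 members were higher by the size rule. By suffix this median was 0.07, 0.07, 0.31 and 0.29, and it was 0.05 with no filter on cells and 0.07 when the described lists were kept out of the variable genes. The median of 18 glycolysis genes was 0.09, with 2 higher and 0 lower. Gpi1 stood at 0.82, Pgam1 at 0.13, Gapdh at -0.03 and Aldoc at -0.97. By suffix the glycolysis median was 0.25, 0.19, -0.03 and -0.01, so its direction differed between suffixes, and thinned to 2000 UMIs the list (median 0.06) was inside the random range. In the other 9 alternatives it stayed above the range, with medians up to 0.19 (median of ratios factors). The median over all genes was -0.15 in this class, or -0.06 with TMM factors. Clusters 0 and 7 held this class in different proportions, with 213 and 269 cells of cluster 0 in suffixes 1 and 2 and 4 and 3 in suffixes 3 and 4.

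Monocyte-like cells had higher inflammatory and lower cell cycle transcripts than the other cells of suffixes 3 and 4, the suffixes with at least 30 such cells. NF-kB and inflammatory genes were higher in 13 of 17 members and lower in 1 (median log2 ratio 0.93), with the chemokines Ccl6 at 3.55 and Ccl9 at 0.58, the receptor Tlr2 at 2.41 and the transcription factor Cebpb higher 2.65-fold. Immediate early and handling stress genes were higher in 11 of 18 members and lower in 3 (median 0.54), with Ier5 at 1.92, Klf6 at 1.61, Hspa8 at 0.44 and Hsp90aa1 at -1.38. Interferon response genes were higher in 10 of 23 and lower in 5 (median 0.26), with Ifitm3 at 3.17, Oasl2 at 1.45, H2-D1 at 0.54 and B2m at 0.16. This list was inside the random range thinned to 2000 UMIs (median 0.13) and as a mean over cells (0.15). G2 and M phase genes were lower in 48 of 52 members (median -2.60) and S phase genes in 40 of 42 (median -1.50), with Nusap1 at -4.30, Kif20b at -3.77, Rad51ap1 at -3.11 and Rrm2 at -2.98. Those with the highest level were Hmgb2 at -1.12, Cks2 at -1.54, Slbp at -0.87 and Tipin at -1.46. The G2 and M phase median was -1.67 with a pseudocount of 5 CPM. Genes of these lists took part in the clustering. Variable genes were 24 of 35 interferon response, 17 of 25 immediate early and handling stress and 16 of 27 NF-kB and inflammatory genes. So were 19 of 54 G2 and M phase, 4 of 42 S phase and 12 of 26 stem and progenitor genes. No cluster met the monocyte-like name without the described lists, so these ratios were not checked apart from the clustering. A monocyte-like class was found without cell cycle, ribosomal and mitochondrial genes, but list ratios were not computed there. DNA repair genes were lower in 18 of 32 (median -0.93), with Brca2 at -2.64, H2afx at -1.95 and Xpc at -1.17. Stem and progenitor genes were lower in 11 of 16 and higher in 3 (median -1.07), with Gfi1 at -3.54 and Angpt1 at -3.27 against Spi1 at 0.60 and Lyl1 at 0.49. Over the alternatives that gave a monocyte-like class, the medians ran from 0.54 to 0.93 for NF-kB and inflammatory, -1.06 to -0.60 for DNA repair and -1.53 to -0.82 for stem and progenitor genes. None of these alternatives left the lists out of the variable genes. Cytarabine handling genes were lower in 6 of 11 and higher in 1 (median -0.50), and the lower ones included both ribonucleotide reductase subunits, Rrm1 at -2.02 and Rrm2. Nme1 stood at -1.54 and Cmpk1 at 0.25, and thinned to 2000 UMIs the list (median -0.21) was inside the random range.

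Neutrophil-like cells had lower interferon response and stem and progenitor transcripts than the other cells of suffixes 3 and 4. Interferon response genes were lower in 17 of 23 members and higher in 0 (median log2 ratio -0.90), with Zbp1 at -3.59, Gbp3 at -3.56, H2-D1 at -0.75 and B2m at -0.70. This median was -1.32 in suffix 3 and -0.73 in suffix 4. The other cells include the monocyte-like cluster 6 (281 and 205 cells) and the interferon-led cluster 13 (20 and 22 cells). How much of the interferon gap they make was not tested. Stem and progenitor genes were lower in 9 of 16 and higher in 1 (median -0.94), with Cd34 at -5.51, Adgrg1 at -2.82, Lyl1 at -0.32 and Spi1 at 0.23. Over the alternatives these 2 medians ran from -1.98 to -0.60 and from -1.54 to -0.60, with the lowest of each when cells were thinned to 2000 UMIs. G2 and M phase genes were higher in 15 of 52 and lower in 4 (median 0.25), with Hmgb2 at 0.73, Kif23 at 0.98, Cks2 at 0.22 and Psrc1 at 0.501 times the other cells. Their median was 0.00 in suffix 3 and 0.54 in suffix 4, and it was -0.13 with no filter on cells. S phase genes (median -0.03) and glycolysis genes (median -0.09) lay above the central 95% of random lists although their medians were below 0, and both medians were above 0 with TMM factors (0.24 and 0.19). With no filter on cells the S phase list (-0.30) was inside the random range. Their members included Slbp at 0.14, Tipin at 0.00 and Brip1 at -1.10, and Gapdh at 0.07, Pgam1 at -0.54, Aldoc at -3.58 and Pfkp at -0.93. The median over all genes was -0.39 in this class, against -0.12 with TMM factors, and list values are read against that shift. A count of lower members does not by itself set a list apart here. Of 79 ribosomal protein genes 78 were lower and 0 higher, and of 63 nuclear encoded oxidative phosphorylation genes 45 were lower and 1 higher. Both medians (-0.55 and -0.43) were inside the random range, while the interferon response and stem and progenitor medians lay below it.

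**Figure D2:**
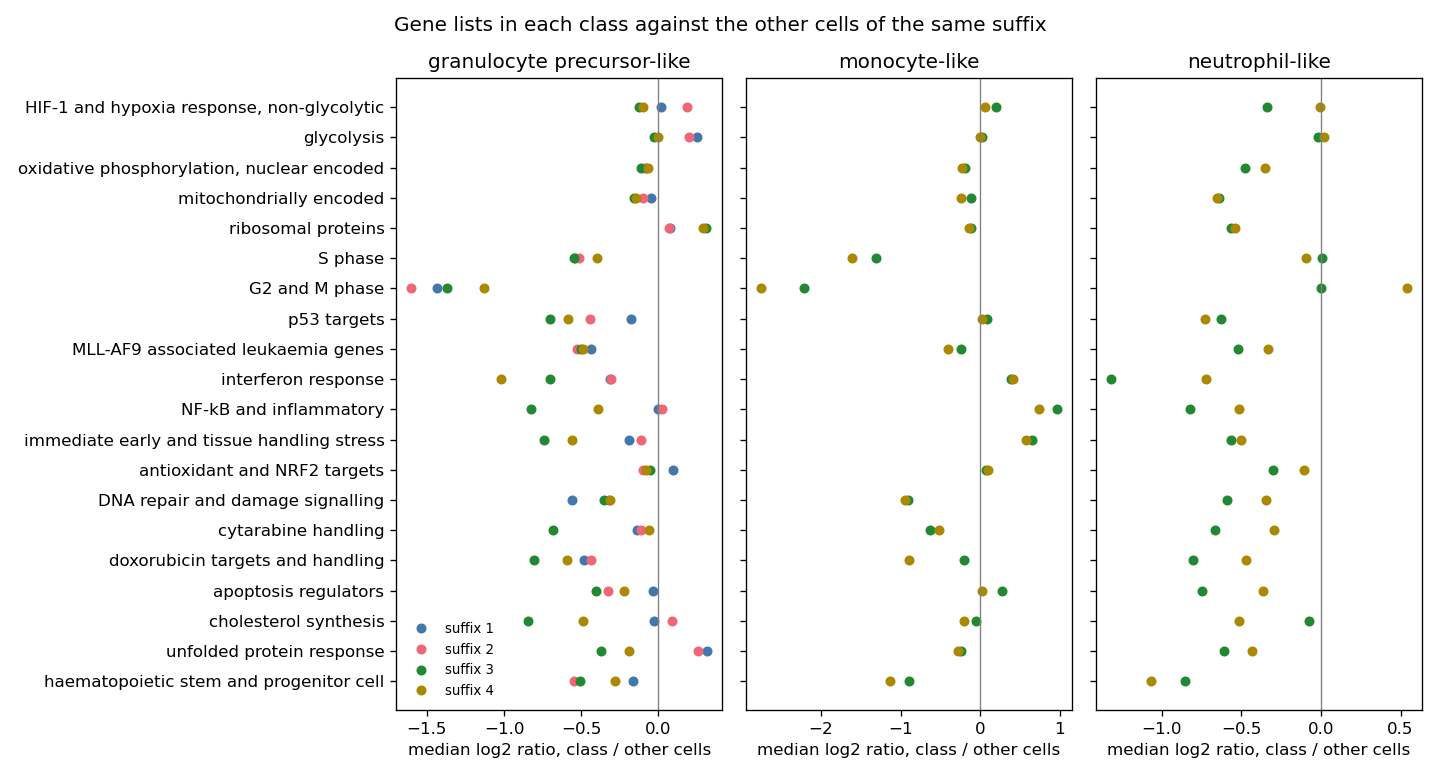
Median log2 ratio of each gene list in a class over the other cells of the same suffix, with 1 point per suffix that had at least 30 cells of the class and an axis scaled to each class. Monocyte-like cells have a median of -2.60 for G2 and M phase genes, and neutrophil-like cells 0.25, which was -0.13 with no filter on cells. The neutrophil-like S phase and glycolysis medians change sign with TMM factors.

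HIF-1 and hypoxia response genes outside glycolysis went both ways in the 3 classes. In monocyte-like cells 9 of 28 measured members were higher and 5 lower, with Lgals3 at 2.50 and Ddit4 at 1.82 against Mif at -1.89 and Egln3 at -1.80. Neutrophil-like cells had 7 higher and 6 lower members, with Mif at -1.80, Lgals3 at -1.15, Ddit4 at -2.13 and Ndrg1 at -1.78. Granulocyte precursor-like cells had 5 higher and 4 lower members, with Lgals3 at -2.48, Anxa2 at -1.11, Ndrg1 at -1.02 and Mif at -0.07. None of these medians (0.04, -0.17 and -0.03) lay outside the central 95% of random lists.

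MLL-AF9 target genes of the HOXA cluster were found in every cluster. Hoxa9, Hoxa7 and Hoxa10 lie on chromosome 6 (Hoxa9 from 52223100 to 52231089, minus strand) and their partner Meis1 on chromosome 11 (18879817 to 19018985, minus strand). Over all suffixes together, their summed level was highest in cluster 10 at 587 CPM (550 to 626). The lowest value, 280 CPM (199 to 382) in cluster 13, rests on 39 UMIs, and its interval covers the levels of clusters 0, 6, 7 and 9 among others. Neutrophil-like cells had 364 CPM (335 to 395), and in suffixes 3 and 4 their level was 0.888 times that of the other cells (0.810 to 0.972). In the list of MLL-AF9 associated leukaemia genes, these cells had 13 of 24 members lower and 0 higher. Its median log2 ratio of -0.43 was inside the random range. Cd34 and Flt3, a progenitor antigen and a cytokine receptor of immature cells, went down to 13.4 CPM (8.32 to 20.5) in neutrophil-like cells, 0.0568 times the level of the other cells (0.0351 to 0.0870). By suffix this ratio was 0.0786 (17 UMIs) in suffix 3 and 0.0263 (4 UMIs) in suffix 4. Pooled over all suffixes, granulocyte precursor-like cells had 0.742 times (0.703 to 0.782) the HOXA and Meis1 level of the other cells and 0.428 times (0.392 to 0.467) that of Cd34 and Flt3. Within suffixes 1 to 4 the HOXA and Meis1 ratio was 0.683, 0.720, 0.722 and 0.767. The Cd34 and Flt3 ratio was 0.478, 0.416, 0.172 and 0.168. In monocyte-like cells the summed levels of both groups of genes lay closer together, at 0.796 times (0.734 to 0.862) and 0.741 times (0.665 to 0.823) the other cells. Cd34 and Flt3 differed there. Cd34 stood at 72.9 and 74.0 CPM in suffixes 3 and 4, against 131 and 133 CPM in the other cells. Flt3 stood at 109 and 94.7 CPM, against 99.0 and 115 CPM. The MLL-AF9 associated list had 12 of 24 members lower and 4 higher in these cells (median log2 ratio -0.35, percentile 2.53 of random lists).

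**Figure D3:**
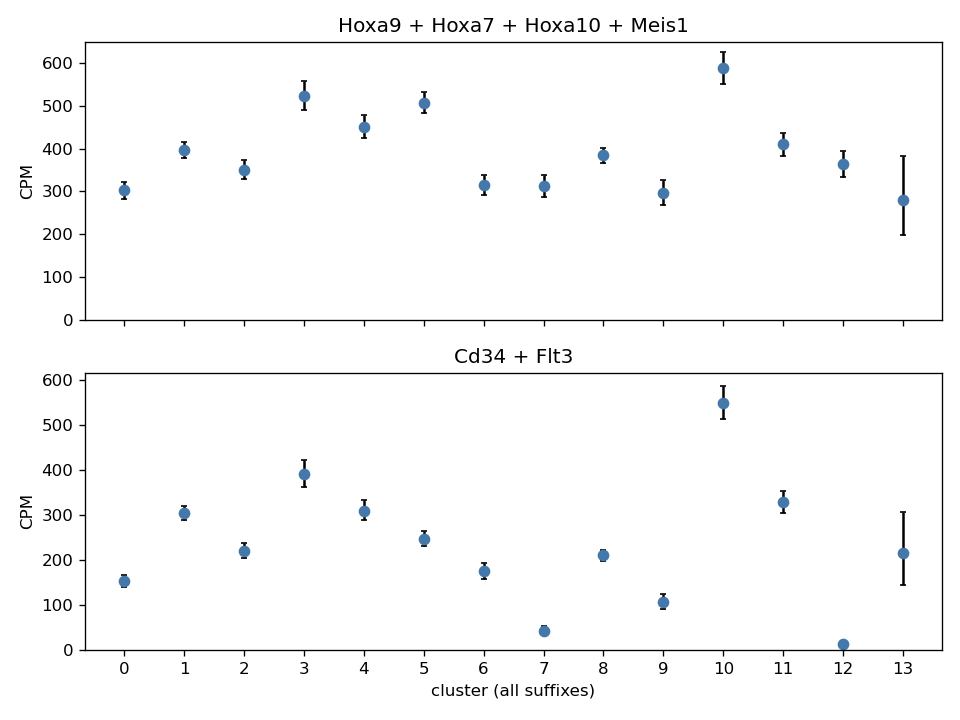
Summed level in CPM of Hoxa9, Hoxa7, Hoxa10 and Meis1 (top) and of Cd34 and Flt3 (bottom) in each cluster, all suffixes together, with exact Poisson 95% intervals. The top panel runs from 280 to 587 CPM, while Cd34 and Flt3 drop to 13.4 CPM in cluster 12, the neutrophil-like cluster.

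Cells with S phase transcripts were common in each suffix. At 2000 UMIs per cell, 86.0% of cells (exact binomial 95% interval 83.9 to 88.0) in suffix 1 had at least 2 UMIs over the S phase list, 81.6% (79.4 to 83.8) in suffix 2, 56.0% (53.5 to 58.5) in suffix 3 and 56.8% (54.1 to 59.4) in suffix 4. Unthinned, these shares were 95.3%, 94.96%, 80.8% and 80.2%. For the G2 and M phase list the thinned shares were 96.2%, 93.9%, 84.6% and 87.4%, close to saturation, and the unthinned shares 99.7%, 99.6%, 97.0% and 98.0%. At a stricter rule of 10 UMIs, chosen after these values were seen, the S phase shares were 27.6%, 18.8%, 10.4% and 11.1% and the G2 and M shares 30.6%, 25.8%, 14.4% and 17.5%. A UMI from these lists can come from free RNA, so these shares are no measure of the number of dividing cells.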

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

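Alternatives that left out the described lists from the variable genes, thinned and clustered again, asked for 10 UMIs or took the mean over suffixes were chosen after seeing the data. Of 520 list medians that an alternative could change, 489 kept the sign of the main value (40 more, means over 2 suffixes, equal their median), and the cause of the differences below was not tested. The S phase median of neutrophil-like cells (main -0.03) was 0.24 with TMM factors, 0.26 with median of ratios factors, 0.12 as a mean over cells and 0.13 thinned to 2000 UMIs. Their glycolysis median (main -0.09) was 0.19, 0.20 and 0.028 under the first 3 of these, and their G2 and M phase median (main 0.25) was -0.13 with no filter on cells. That G2 and M phase median was 0.52 with TMM factors, 0.54 with median of ratios factors and 0.44 as a mean over cells. It was 0.42 thinned to 2000 UMIs and 0.11 without the described lists. Lists above the random range in this class (main 3) were 5 as a mean over cells, with a pseudocount of 5 CPM and without the described lists. Lists below it (main 2) were 4 with no filter and without the described lists. Without the described lists 5 lists lay above the range in granulocyte precursor-like cells (main 2), and as a mean over cells 8 lay below it in monocyte-like cells (main 5). The median share of granulocyte precursor-like cells (main 13.9%) was 7.94% at resolution 0.5, 3.09% without cell cycle, ribosomal and mitochondrial genes, 4.70% with no filter, 11.5% without the described lists and 11.9% thinned and clustered again. For monocyte-like cells (main 7.69%) it was 20.98% at resolution 0.5, 6.12% without cell cycle, ribosomal and mitochondrial genes and 10.6% thinned and clustered again. No cluster met that name with no filter or without the described lists. For neutrophil-like cells (main 4.03%) it was 5.59% without cell cycle, ribosomal and mitochondrial genes, 5.72% with no filter and 6.13% without the described lists. The S phase share (main 69.2%) was 87.9% unthinned, 49.5% at 1000 UMIs, 54.6% for 3 UMIs and 14.9% for 10 UMIs. The G2 and M phase share (main 90.6%) was 98.8%, 67.6%, 78.5% and 21.6%. Other minimum levels for counting genes that differ between samples and the removal of lymphoid, erythroid or stromal clusters were not run. No count between samples was made and no cluster had such a name. Minimum levels other than 5 CPM for list members were not run either. With means over suffixes, which were computed first, 9 lists lay below the random range in granulocyte precursor-like cells (main 7).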

Other observations

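The 5 tests of explanations below and the rule of 10 UMIs were chosen only after the values they bear on had been seen. G2 and M phase transcripts differed between the maturing classes. At 2000 UMIs per cell, 20.3% (13.8 to 28.1) of neutrophil-like cells in suffix 3 and 25.7% (17.6 to 35.4) in suffix 4 had at least 10 UMIs over the G2 and M phase list, against 13.8% (12.1 to 15.7) and 16.9% (14.9 to 19.0) of the other cells. Monocyte-like cells had 1.82% (0.593 to 4.19) and 1.49% (0.309 to 4.30) in the same suffixes, against 17.0% and 20.3% of the other cells. For both classes the other cells include clusters 4, 5 and 8, which were led by cell cycle genes. For the S phase list the neutrophil-like shares were 14.3% and 10.9% against 10.1% and 11.1% of the other cells, so no gap was seen in suffix 4. The intervals of neutrophil-like and other cells overlap for both lists in each of the 2 suffixes. The G2 and M phase median of neutrophil-like cells was -0.13 with no filter on cells (main 0.25).

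Eosinophil granule genes were spread unevenly inside cluster 9. Prg2, which encodes major basic protein, had 417 UMIs in 12 of 136 cells of suffix 3, with 164 UMIs in a single cell, and 25 UMIs in 2 of 126 cells of suffix 4. Prg3 had 94 UMIs in 29 of the 136 cells and 79 UMIs in 30 of the 126 cells. Most Prg2 UMIs of these suffixes in the cluster were thus in few cells. In cluster 13, with 42 cells in suffixes 3 and 4, MHC class II genes (Cd74 and H2-Aa) stood among the 10 leading genes beside Ifit3 and Isg15.

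Several values fell into 2 sets of suffixes, with no condition known for either. Granulocyte precursor-like shares were 23.6% and 28.6% in suffixes 1 and 2 and 4.12% and 3.49% in suffixes 3 and 4. Most of this gap lay in cluster 0, at 18.1%, 21.5%, 0.246% and 0.213% of suffixes 1 to 4. Cluster 7, with 10 raised granulocyte precursor markers against 6 in cluster 0, made up 5.45%, 7.11%, 3.88% and 3.27%. Summed granulocyte precursor genes differed less than the shares, at 17810, 21058, 9565 and 10244 CPM. Summed neutrophil genes were 1029, 1665, 18585 and 13441 CPM and summed monocyte genes 4156, 5255, 10403 and 11462 CPM in suffixes 1 to 4. S phase genes summed to 3842, 3142, 2197 and 2262 CPM. Glycolysis genes did not follow that split, at 5858, 7289, 5084 and 6146 CPM. Xist was at 1050, 1062, 1288 and 1323 CPM, and 4 Y-linked genes had 0 UMIs among 34865438.

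HOXA genes and Meis1 persisted in neutrophil-like cells at 0.888 times (0.810 to 0.972) the level of the other cells, which goes against normal neutrophils that passed the GFP sort, if those lack these transcripts. This holds for these 4 genes and not for the whole list of MLL-AF9 associated leukaemia genes. In that list 13 of 24 members were lower and 0 higher (median log2 ratio -0.43), near the median over all genes of -0.39. Free RNA or doublets would bring Cd34 and Flt3 along, and these stood at 0.0568 times (0.0351 to 0.0870), or 0.0786 and 0.0263 times in suffixes 3 and 4. A mixture with 0.5 or more normal cells would lower the share of cells with a UMI of the 4 genes. It would be at most 0.5 times that of the other cells. This holds if normal cells lack these transcripts and leukaemia cells of the mixture show such a UMI no more often than the other cells. The share was 41.5% (35.1 to 48.1) against 51.9% (1418 of 2732 cells) at 2000 UMIs per cell. Neither condition was checked, as no normal neutrophils were measured for comparison and leukaemia cells of a mixture were not told apart. The share of normal cells in a mixture therefore stays open. As a hypothesis that these tests do not decide, at least part of the neutrophil-like cells may be leukaemia cells; reading GFP or the fusion transcript in them would test it, and the table holds neither.

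Neutrophil-like shares of 0.426%, 0.799%, 8.31% and 7.25% in suffixes 1 to 4 differed 19.5-fold from lowest to highest. After thinning every cell to 2000 UMIs and clustering again, the shares were 0.524%, 0.9748%, 8.54% and 6.85%, still 16.3-fold apart, which goes against depth per cell as the cause. A batch cannot be told apart from a treatment or genotype here, because suffixes have no label. No biological explanation was tested.

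The glycolysis list was 1.43 times as high in suffix 2 as in suffix 3. With equal weight for the 7 clusters that had 30 or more cells in each suffix, the ratio was 1.31 (1.29 to 1.33), and suffix 2 was higher in 7 of the 7 clusters. The excess was 72.1% of that in all kept cells. These 7 clusters leave out the cells of all other clusters, so that share does not measure the effect of the mix alone. For the cells of these 7 clusters, a different mix was therefore not the whole cause, and how much it accounts for was not measured. This bound was set after the ratio had been computed, and an earlier bound, on the share of the excess left, had not decided the question. No biological explanation was tested, since the suffixes have no label.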
